A study of Mus musculus with 8 samples.

How the data were processed

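Per the labels, the libraries came from germ cells of Sam68 knockout mice on a C57BL/6 background. Per the labels' protocols, spermatocytes and spermatids of 12-week-old males were separated by sedimentation at unit gravity, RNA was treated with DNase, and stranded libraries of polyadenylated RNA were made. There were 8 libraries, 4 of spermatocytes and 4 of spermatids, all labelled Sam68 -/-. Replicates were numbered in the order of their records, and nothing in the labels says that libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. The deposited table holds 8 further columns of per-sample values, which were not used, and no comparison of genotypes was made.

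The deposited signal is the read count per gene model divided by a size factor per library; the table's own name announces DESeq normalization, its header gives mm10 coordinates, and the submitters' processing notes name FastQC, Picard, SAMtools, STAR 2.4.0, DESeq and the mm10 build. The counting tool, its strand setting and any filter are not given in the sources used here. Reads of antisense or overlapping genes may therefore be mixed, and near-identical gene copies may share reads. Within each library every deposited value was a whole multiple of a fixed step: 100% of the values above 0 lay within 10% of the step from a whole number of reads. Dividing by the step gave back whole reads, 49000266 to 93975960 per library. With 3 reads taken as the floor, the floor lies between 2.42 and 4.50 normalized counts per library, and it covers counting error alone.

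The table lists 56324 gene models, of which 32111 carry no symbol and 636 share a symbol with another model. Models with at least 10 normalized counts in at least 4 libraries were tested, which left 28735, of which 10238 have no symbol. Values were taken as log2(normalized count + 1). The added 1 lowers the fold change of low genes. A single library with very few reads can instead enlarge it beyond the ratio of mean counts. For Tgif2lx1 the fold was 93.2 from log2 values and 33.6 from mean counts. The main test was limma 3.58.1 with trend and robust variance moderation in R 4.3.3, spermatids against spermatocytes over all 8 libraries, with no covariate. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 fold change of at least 1, and adjusted p-values of single genes are from this limma test unless stated. The test, the gene lists, the rule for named genes and the first group of alternatives below were fixed before the data were examined.

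There were 16 gene lists with 401 genes, of which 379 were matched, 16 of them through a synonym in the RefSeq table. Where several models shared a symbol, the one with the highest mean was used and is called a model of that gene. Lists were tested with limma's camera at a preset correlation of 0.01, together with the X-linked genes, the ribosomal protein genes and the models of the mitochondrial genome, 19 sets in all. Symbols of mitochondrially encoded genes were to define the last set, but the table gives its mitochondrial models no such symbols, so models on chromosome M were used. Of 18 fixed pairs of a germline gene and a broadly expressed relative, 17 could be tested. The log2 ratio was compared by an exact two-sided permutation test whose smallest p is 0.0286, adjusted by the Benjamini-Hochberg method over the 17 pairs. Named genes were Khdrbs1, the 5 largest rises and 5 largest falls among called genes with a mean of at least 500 in the higher group, no overlap between groups and no symbol of a Gm, Rik, AC or AL gene model, the 2 called members of each list with the largest fold change plus the largest in the other direction (or the most abundant member where none was called), and the members of the pairs. Other list members in the text were chosen after their values were seen.

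Pairs of libraries within a cell type differed by more than sampling noise, since the smallest chi-square per degree of freedom was 12.2. The test was checked on simulated counts with the means and library sizes of the real genes and 200 changed genes. With the dispersions of both groups, 37.0% of 100 genes changed 2-fold and 87.0% of 100 genes changed 4-fold were called among 27919 genes. With the larger dispersions of the spermatocyte libraries alone these shares were 3.00% and 73.0% among 27786 genes. Unchanged genes made up 8.63% and 3.80% of the genes at an adjusted p below 0.05 in these simulations. The share of 8.63% lies above the 0.05 that the adjustment aims at. Changes near 2-fold were often missed in these simulations. With only 200 changed genes the adjusted p is stricter there than in the data, where 20764 of 28735 models passed it. The recovered shares therefore do not carry over to the data.

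The first group of alternatives held pseudocounts of 0.5 and 8, other filters, TMM, median-of-ratios and quantile scaling, limma without trend and robust moderation, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered read counts, other fold rules, an estimated correlation in camera, and each library left out. Alternatives chosen after seeing the data were equal total reads, leaving out spermatocyte libraries 3 and 4 together, and a correction for transcript GC content. GC content and length are means over GENCODE M21 transcripts, matched by symbol for 17045 of 18497 tested models with a symbol. Figures were drawn with matplotlib in Python.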

Results

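RNA of spermatocytes and spermatids from mice labelled as knockouts of Sam68, an RNA-binding protein encoded by Khdrbs1, was profiled in 4 libraries of each cell type. The series title concerns Sam68 and the processing of 3' ends during germ cell differentiation. With libraries of a single genotype analysed here, the comparison made was the change between both cell types under this label. Read totals lay between 49000266 and 78060212 in spermatocyte libraries and between 60673309 and 93975960 in spermatid libraries. Khdrbs1, on chromosome 4 from 129703169 to 129742304 of mm10, had 4133 ± 676 normalized counts in spermatocytes and 815 ± 233 in spermatids (SD, n = 4 each; log2 fold change -2.37 ± 0.22 SE, limma adjusted p = 1.1e-06). Among tested models it stood at percentile 89.5 in spermatocytes and 70.6 in spermatids. Its reads are summed over the whole gene model, which may include parts outside the deletion, and no library of another genotype was analysed here, so this level does not check the genotype labels.

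Spermatids and spermatocytes differed over most of the transcriptome. Spermatids held far more RNA of the protamine genes Prm1 and Prm2, the hyaluronidase gene Spam1 and the sperm calcium channel gene Catsper3, and far less for the piRNA protein Piwil1, the meiotic kinase Cdk2 and the hnRNP proteins Hnrnpl and Hnrnpm. Of 28735 gene models tested, 17896 were called, 9333 higher and 8563 lower in spermatids. At any fold size 20764 models passed the adjusted p. Over the 17045 genes with a known GC content 62.6% of calls were higher, and 46.3% after a correction for GC content that was chosen after seeing the data. The correction removes any trend with GC content in each library. It cannot tell a technical bias from a real difference between the cell types that follows GC content. Spearman correlations lay between 0.955 and 0.984 within spermatocytes, between 0.976 and 0.991 within spermatids, and between 0.694 and 0.746 across cell types. The first principal component held 87.1% of the variance and separated the cell types. The deposited values summed to more in each spermatid library than in any spermatocyte library (exact two-sided permutation p = 0.0286, n = 4 each). The median log2 fold change of all tested genes, -0.01, became -0.44 when scaled to equal total reads and -0.36 with quantile normalization, and over the genes with a known GC content it went from 0.25 to -0.31 with the GC correction, so that changes after this correction are to be read against that shift.

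The named genes with the largest rises were Tgif2lx1, Slxl1 and Mageb5 on the X chromosome, the lectin gene Clec4a2 on chromosome 6 and the histone gene Hist1h3a on chromosome 13. Slxl1 rose from 194 ± 124 to 10513 ± 2007 normalized counts (SD, n = 4 each; log2 fold change 6.51 ± 0.92 SE, limma adjusted p = 8.4e-05). Tgif2lx1 rose by 6.54, Clec4a2 by 6.40, Mageb5 by 6.28 and Hist1h3a by 6.22 on the log2 scale. Spermatocyte library 4 had 0 reads of Tgif2lx1 and of Mageb5, and without it the log2 changes were 4.65 for Tgif2lx1, 4.64 for Mageb5, 5.34 for Slxl1 and 5.43 for Clec4a2. Without spermatocyte libraries 3 and 4 they were 4.78, 4.52, 5.28 and 4.96, and after the GC correction 5.71, 4.53, 4.71 and 5.29, in the same order. The markers of macrophages and blood cells, in which Clec4a2 is known to be expressed, had mean log2 levels of 4.93 to 5.46 in spermatocyte libraries and 7.77 to 8.72 in spermatid libraries. Several of the genes with the largest rises belong to families with near-identical copies, so their reads are uncertain. The largest falls were of Fam174b, from 4836 ± 642 to 99.2 ± 15.0 (SD, n = 4 each; log2 fold change -5.60 ± 0.20 SE, limma adjusted p = 9.5e-10), Pou5f2 (-5.56), AI467606 (-5.51), Slc9a2 (-5.46) and a model of the aromatase gene Cyp19a1 (-5.45). Slc9a2 was at 0 in spermatid library 2, and its change was -4.35 without that library, -4.75 without spermatocyte libraries 3 and 4 and -6.04 after the GC correction, where the Cyp19a1 model was at -6.10. In spermatocyte libraries 1 to 4 Slc9a2 had 179, 403, 1022 and 508 normalized counts. The Sertoli cell markers had mean log2 levels of 9.53, 10.18, 11.67 and 10.53 in these libraries. Among spermatid libraries these markers were also lowest in library 2.

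Genes for the compaction of the sperm nucleus rose together. Of 13 tested members 11 rose and 1 fell, with the same counts when adjusted over the list alone. Prm1 and Prm2, which encode protamines, rose by 4.27 and 4.06 on the log2 scale, and Tnp1, a transition protein gene, by 4.28. Chd5, a chromatin remodeler, rose most, from 2198 ± 324 to 65121 ± 15431 normalized counts (SD, n = 4 each; log2 fold change 4.87 ± 0.20 SE, limma adjusted p = 1.6e-09), followed by Prm3 (4.78). Kdm3a, a histone demethylase, fell by 1.14, and was at -1.92 after the GC correction. The list had a median of 4.27 and a camera adjusted p = 2.4e-04, and adjusted p = 0.38 with an estimated correlation.

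Acrosome genes rose in 15 of 27 cases and fell in 1, and the counts adjusted over the list alone were the same. The hyaluronidase genes Spam1 and Hyal5, which are neighbours on chromosome 6 and belong to the same family, rose by 5.87 and 5.73 on the log2 scale, and Acrv1 by 5.40. After the GC correction these changes were 4.34 for Spam1, 4.40 for Hyal5 and 4.53 for Acrv1, and Spam1 was at 5.25 without spermatocyte libraries 3 and 4. Gopc, a Golgi protein gene, fell by 2.80, and was at -3.73 after the GC correction. The median of the list was 1.35 (camera adjusted p = 1.2e-04, and adjusted p = 0.38 with an estimated correlation). It was 0.78 with quantile normalization, 0.56 after the GC correction and 0.88 without spermatocyte libraries 3 and 4.

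Among 39 tail and motility genes 25 rose and 5 fell, with the same counts when adjusted over the list alone. Catsper3, a subunit of the sperm calcium channel, rose from 186 ± 37.7 to 7877 ± 1199 normalized counts (SD, n = 4 each; log2 fold change 5.40 ± 0.21 SE, limma adjusted p = 1.1e-09), and Sun5 rose by 5.39. The members that fell were Rsph1 and the axonemal dynein heavy chains Dnah1, Dnah2, Dnah8 and Dnah17. Dnah2 fell by 2.37. The median of the list was 3.07 (camera adjusted p = 3.8e-05, and adjusted p = 0.38 with an estimated correlation). Regulators of spermiogenesis rose in 10 of 18 cases and fell in 2, with the same counts when adjusted over the list alone, led by Fhl5 (5.19) and Camk4 (4.90) on the log2 scale, while Gmcl1 fell by 3.22. Fhl5 was at 4.40 and Gmcl1 at -3.98 after the GC correction. Their median was 1.43 (camera adjusted p = 0.027), and adjusted p = 0.38 with an estimated correlation. The camera adjusted p was 0.060 with a filter of 50 normalized counts, 0.068 with quantile normalization, 0.073 over only the genes with a known GC content, 0.064 over these after the GC correction and 0.052 without spermatocyte libraries 3 and 4.

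Genes of the piRNA pathway fell in 10 of 21 cases and rose in 3, with the same counts when adjusted over the list alone. Piwil1, an Argonaute protein that binds piRNAs, fell from 136863 ± 22459 to 4256 ± 1063 normalized counts (SD, n = 4 each; log2 fold change -5.02 ± 0.20 SE, limma adjusted p = 1.4e-09). Tdrd5 fell by 4.53, and was at -5.20 after the GC correction, and Pld6 fell by 3.35. The members that rose were Gtsf1 (1.47), Rnf17 (1.19) and Gm13718 (2.03). Rnf17 was at 0.85 and not called without spermatocyte library 4. With quantile normalization Gtsf1 (0.90) and Rnf17 (0.64) were below the fold threshold, as was Rnf17 with equal total reads (0.75). After the GC correction 0 of 20 rose and 13 fell, with Gtsf1 at 0.76, Rnf17 at -0.25 and Gm13718 without a GC value. The list had a median of -0.97 and a camera adjusted p = 0.021, and adjusted p = 0.21 with an estimated correlation. The median was -1.46 with quantile normalization and -1.79 after the GC correction.

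Meiotic genes went both ways. Of 21 synaptonemal complex and cohesin genes 7 rose and 3 fell. Rec8, the meiotic kleisin of cohesin, rose from 624 ± 215 to 14853 ± 1755 normalized counts (SD, n = 4 each; log2 fold change 4.62 ± 0.22 SE, limma adjusted p = 4.3e-09), and Tex11 rose by 3.27. Sycp2 fell by 1.26 and 1700123I01Rik by 2.15. Sycp1 had 14935 ± 10551 in spermatocytes and 11072 ± 2500 in spermatids (SD, n = 4 each) and was not called as deposited. The median of the list was -0.11, its mean 0.52 and its camera direction up (adjusted p = 0.65). Spermatocyte library 4 held 1653 normalized counts of Sycp1 against 12680 to 26690 in the other spermatocyte libraries. Without spermatocyte libraries 3 and 4, an alternative chosen after seeing the data, 7 members rose and 6 fell, Sycp3 (-1.38) and Hormad1 (-1.49) among them, and Sycp1 was at -0.50 and not called. Without library 4 alone and with equal total reads 7 rose and 7 fell, and after the GC correction 6 of 17 rose and 7 fell. With that correction Sycp1 was called lower (-2.02, limma adjusted p = 1.9e-04), as were Sycp3 (-3.18), Hormad1 (-3.24) and Sycp2 (-3.72), and Tex11 was at 1.70. Since the correction may also remove real differences that follow GC content, these values do not decide whether the genes fell.

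Of 23 recombination genes 6 rose and 5 fell, and after the GC correction 3 of 22 rose and 10 fell. A model of Tex15 rose by 4.91 on the log2 scale, and Dmc1, the meiotic recombinase, by 2.50. Mlh3, which acts at crossovers, fell by 3.16 and Spo11, which makes meiotic DNA breaks, by 1.36. After the GC correction the Tex15 model was at 3.87, Dmc1 at 1.59, Mlh3 at -3.94 and Spo11 at -2.11. Of 25 genes of the meiotic divisions 7 rose and 11 fell. Ccnb3 rose by 4.60 and Cdk2 fell by 3.21. Without spermatid library 2, 4 of the division genes rose, and Ccnb3 was at 3.80 without spermatocyte library 2 and at 3.34 after the GC correction. With equal total reads 4 division genes rose and 13 fell, and after the GC correction 4 of 24 rose and 11 fell. The camera adjusted p was 0.98 for recombination (median 0.30, and -0.14 with equal total reads, -0.058 with quantile normalization and -0.78 after the GC correction) and 0.27 for the divisions (median -0.66). Each of these meiotic lists, that of the synaptonemal complex included, gave the same counts when adjusted over the list alone.

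Factors of cleavage and polyadenylation, the step named in the series title, rose in 5 of 30 cases and fell in 7, with the same counts when adjusted over the list alone. Cstf2, the X-linked subunit of the cleavage stimulation factor, rose from 547 ± 85.9 to 13677 ± 2807 normalized counts (SD, n = 4 each; log2 fold change 4.63 ± 0.20 SE, limma adjusted p = 2.0e-09). Its autosomal relative Cstf2t fell from 6366 ± 526 to 1340 ± 295 (SD, n = 4 each; log2 fold change -2.27 ± 0.19 SE, limma adjusted p = 4.1e-07). Cpsf4l rose by 5.09 and Cpsf4 fell by 1.97. The median of the list was 0.06 with a camera direction down (adjusted p = 0.98), and the median was negative with equal total reads (-0.38), quantile normalization (-0.32) and the GC correction (-0.44). After the GC correction 2 of 29 rose and 9 fell, with Cstf2t at -3.00.

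Among genes of splicing more fell than rose, and most were not called. Of 47 splicing regulators 20 fell, 3 rose and 24 were not called, and of 20 U1 and Sm proteins 8 fell, 0 rose and 12 were not called, with the same counts when adjusted over the list alone in both. Hnrnpl fell by 3.37 on the log2 scale, Hnrnpm by 3.04, Snrpb by 2.08 and Luc7l2 by 1.69. Rbmx, which is X-linked, rose by 2.20. The median was -0.79 for the regulators (camera adjusted p = 0.0045, and adjusted p = 0.38 with an estimated correlation) and -0.55 for the U1 and Sm proteins (camera adjusted p = 0.021, and adjusted p = 0.21 with an estimated correlation). Both medians were lower with equal total reads (-1.23 and -0.99) and the GC correction (-1.55 and -1.09), and that of the regulators was -1.20 with quantile normalization. After the GC correction 31 of 46 regulators fell and 1 rose, with Hnrnpm at -3.72 and Rbmx at 1.53, and Luc7l2 was at -2.68.

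X-linked genes, whose transcription is silenced in pachytene spermatocytes, were mostly higher in spermatids. Of 831 tested X-linked models 555 (66.8%) were higher and 100 (12.0%) lower, against 31.4% higher and 30.4% lower of 27846 autosomal models. Adjusted over the list alone, 556 were higher and 102 lower. The odds ratio for a higher call was 4.39 (two-sided Fisher's exact test, p = 6.4e-94), where genes are not independent replicates. The median log2 fold change was 2.71 on the X chromosome and -0.05 on the autosomes. The camera adjusted p was 1.4e-10, and adjusted p = 0.38 with an estimated correlation. The X-linked median was 1.26 with no filter on low values and 1.68 after the GC correction. On the Y chromosome 33 of 35 models were higher.

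**Figure D1:**
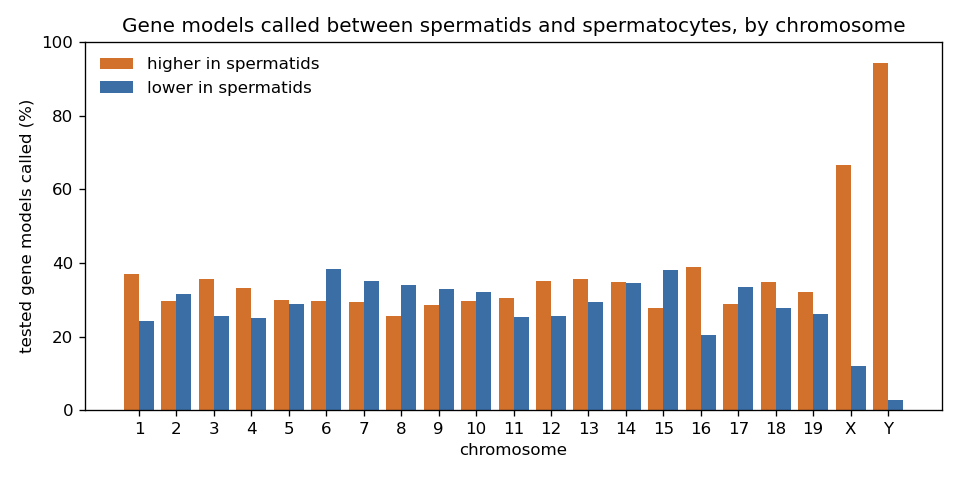
Bars give the percent of tested gene models called higher (orange) or lower (blue) in spermatids on each chromosome, from 4 libraries of each cell type. The X chromosome reached 66.8% higher and the Y chromosome 94.3% higher.

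Germline genes and their broadly expressed relatives changed their balance in 11 of 17 pairs by the exact permutation test (adjusted p = 0.044 each, n = 4 libraries of each cell type), and the ratio of the germline gene was higher in spermatids in 6 of these and lower in 5. The log2 ratio of Gapdhs to Gapdh, glycolytic enzymes, went from 1.61 ± 0.89 to 8.94 ± 0.37 (SD, n = 4 each), with ratios of 2.80, 1.78, 0.80 and 1.06 in spermatocyte libraries 1 to 4. Gapdh itself had a log2 fold change of -2.65, and -1.84 without spermatocyte libraries 3 and 4, and had 498, 786, 2187 and 1710 normalized counts in these libraries, beside mean log2 levels of the Sertoli cell markers of 9.53, 10.18, 11.67 and 10.53. The log2 ratio of Taf7l to Taf7 went from -3.54 ± 0.41 to 1.39 ± 0.23. The ratios that were lower in spermatids were those of Cstf2t to Cstf2, from 3.55 ± 0.29 to -3.35 ± 0.63, of the glucose transporters Slc2a3 to Slc2a1, from 10.34 ± 0.94 to 6.03 ± 0.83, and of Cetn1 to Cetn2 (log2 difference -3.07), Ccna1 to Ccna2 (-1.89) and Rbmxl2 to Rbmx (-1.35). Of these germline genes Cstf2t (log2 fold change -2.27) and Slc2a3 (-3.62) fell. Cetn1 (-0.018), Ccna1 (-0.12) and Rbmxl2 (0.84) were not called, while Cetn2 (3.05), Ccna2 (1.78) and Rbmx (2.20) rose. The ratio of Papolb to Papola was 4.75 ± 0.77 in spermatocytes and 4.73 ± 0.20 in spermatids, with both genes called higher in spermatids. Neither was called after the GC correction (log2 fold changes 0.30 for Papolb and 0.60 for Papola), nor was Papolb without spermatocyte libraries 3 and 4 (0.99). No pair passed when any of the 4 spermatid libraries was left out (smallest adjusted p between 0.088 and 0.097 by the exact test), since 5 pairs then reached the smallest p against 11 with all libraries.

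**Figure D2:**
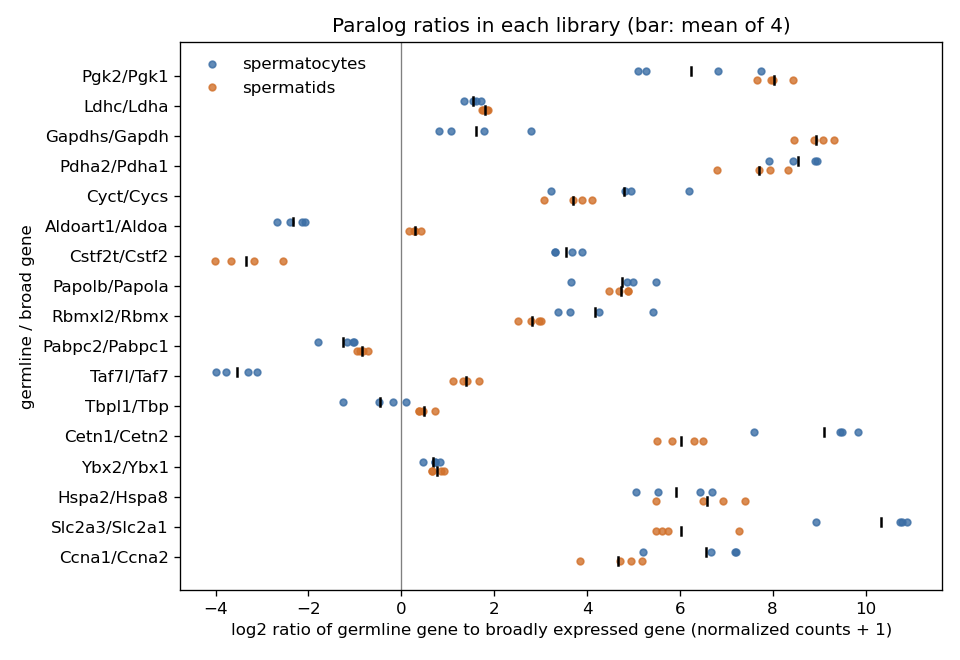
Each point is the log2 ratio of a germline gene to its broadly expressed relative in a library of spermatocytes (blue) or spermatids (orange), and black bars are means of 4. Gapdhs/Gapdh moved from 1.61 to 8.94 and Cstf2t/Cstf2 from 3.55 to -3.35.

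Markers of other testis cells differed between the fractions. The mean log2 level of the Sertoli list was 9.53, 10.18, 11.67 and 10.53 in spermatocyte libraries 1 to 4, and 7.64, 6.43, 7.51 and 7.57 in spermatid libraries 1 to 4. All 22 Sertoli cell markers were lower in spermatid libraries, with a median of -3.37 (camera adjusted p = 8.3e-06, and adjusted p = 0.38 with an estimated correlation). Clu had 56079 ± 38507 normalized counts in spermatocyte and 2717 ± 1335 in spermatid libraries (SD, n = 4 each; log2 fold change -4.35 ± 0.55 SE, limma adjusted p = 2.0e-05), and Fshr fell by 4.40. Of 11 Leydig cell markers 10 were lower (median -2.90), with Cyp11a1 at -4.40 and Ptgds at -3.80 (camera adjusted p = 0.0024, and adjusted p = 0.38 with an estimated correlation). Cyp11a1 had 743 ± 285 normalized counts in spermatocyte and 58.6 ± 44.4 in spermatid libraries (SD, n = 4 each), with 1.87 in spermatid library 2. Without that library the log2 changes were -3.23 for Cyp11a1 and -3.20 for Ptgds. Without spermatocyte libraries 3 and 4, 19 of the 22 Sertoli markers and 10 Leydig markers were lower, the Sertoli median was -2.72 and Clu was at -3.61. Fshr was at -5.11 after the GC correction.

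Among markers of other cells more were called higher than lower in spermatid libraries. Whether RNA of such cells in the spermatid fractions accounts for these or for other higher calls was not tested. Of 18 markers of peritubular myoid and endothelial cells 14 were higher and 2 lower, led by the collagen-binding proteoglycan gene Dcn (4.27) and Col1a2 (3.65), with Pecam1 at -1.52 (camera adjusted p = 0.0086, and adjusted p = 0.21 with an estimated correlation). Of 12 macrophage and blood markers 9 were higher and 1 lower, and 10 and 1 when adjusted over the list alone. C1qa rose by 6.06 and Csf1r by 5.63, and Alas2 of red cell precursors fell by 3.98 (camera adjusted p = 0.0086, and adjusted p = 0.38 with an estimated correlation). Of 21 spermatogonial genes 10 were higher and 2 lower, with Pou5f1 at 4.24 and Id4 at -3.75 (median 1.05, camera adjusted p = 0.18, and 0.046 with no filter on low values). Dcn was at 3.22, Col1a2 at 2.99 and Id4 at -4.77 after the GC correction, and Alas2 was at -3.36 without spermatocyte libraries 3 and 4. The other lists of testis cell markers gave the same counts when adjusted over the list alone.

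**Figure D3:**
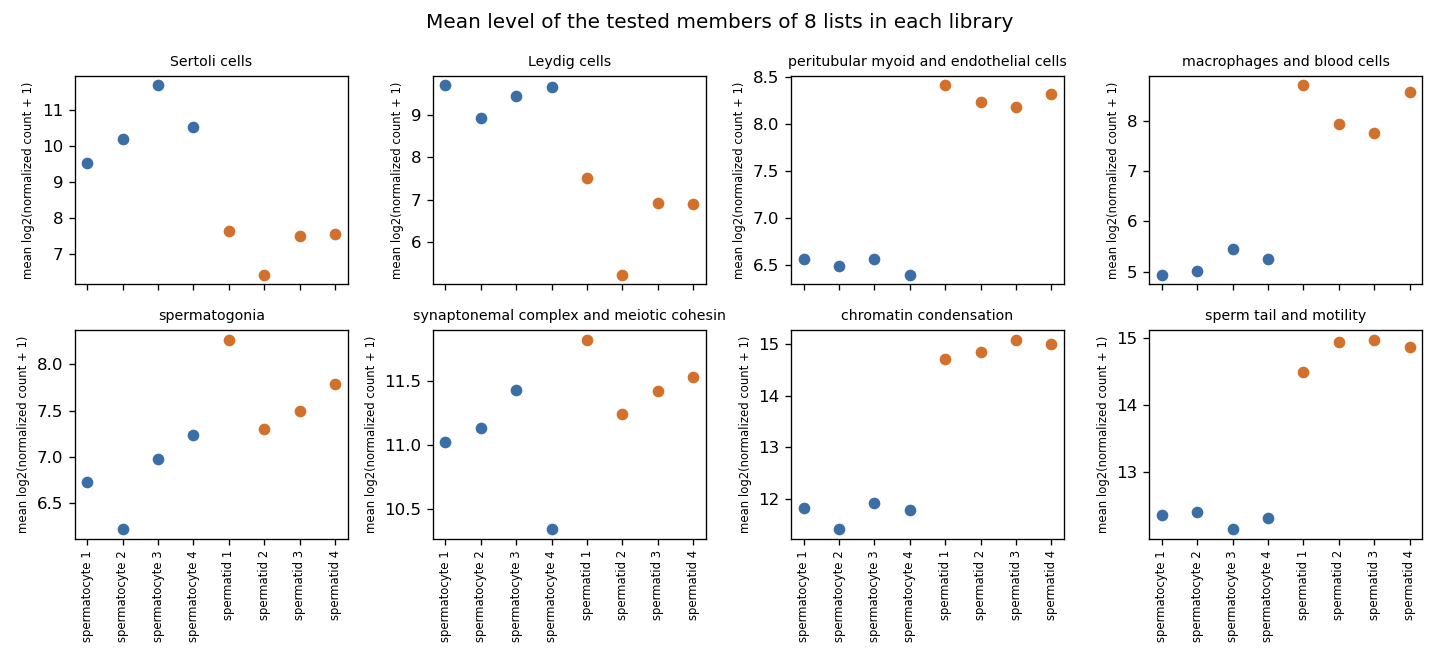
Each point is the mean log2(normalized count + 1) of the tested members of a list in a library of spermatocytes (blue) or spermatids (orange). All 22 Sertoli markers were called lower in spermatids, and 11 of 13 chromatin condensation genes higher.

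Ribosomal protein genes rose in 2 of 81 cases and fell in 9 (median -0.18, camera adjusted p = 0.19), and 1 rose and 9 fell when adjusted over the list alone. Without spermatocyte library 2 or spermatid library 1, 0 of them rose, and without spermatocyte library 1 or spermatid library 3 or 4, 1 rose. Of 13 gene models of the mitochondrial genome 0 rose and 3 fell (median -0.86, camera adjusted p = 0.23), and 0 rose and 0 fell when adjusted over the list alone. Without spermatocyte library 2 or 3, 0 fell, and without spermatid library 2 or 4, 1 fell. Without spermatocyte library 4, 10 of them fell and their median was -1.50 (camera adjusted p = 0.0068). The set passed camera in 2 of 19 alternatives, this one included. With spermatocyte libraries 3 and 4 left out 9 fell, and with equal total reads 6 fell. The ribosomal protein genes passed camera with quantile normalization (median -0.57, adjusted p = 0.012) and with equal total reads (-0.62, adjusted p = 0.016), over only the genes with a known GC content (adjusted p = 0.015), and over these after the GC correction (-0.64, adjusted p = 0.0026). With equal total reads 0 of 81 rose and 18 fell, and after the GC correction 0 of 80 rose and 20 fell. Reads counted on gene models of chromosome M made up 3.30 ± 2.08% in spermatocytes and 1.02 ± 0.351% in spermatids (SD, n = 4 each; exact two-sided permutation p = 0.0857), and 0.946% in spermatocyte library 4.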

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

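The tests of Sertoli co-variation and of a shift of all genes were chosen after the results were seen. So were those of both early germ cell explanations and of a wrong label. The count of single genes that differ like the Sertoli markers was also chosen then. The test of other splits was chosen before. Those of GC content, length, depth and Sertoli RNA behind other genes were chosen before they were run. The patterns they address, spermatocyte library 4 apart and Sertoli markers highest in spermatocyte library 3, were known by then. Of 248 groups of 4 libraries examined, on the log2 scale for genes, 20 held a library that stood apart from the others by Dixon's test at the 0.05 level, and chance gives about 5% of groups. That share holds for groups not chosen by their values. Many named genes were chosen for large log2 changes, which a very low library enlarges. Tgif2lx1 was at 6.54 with all libraries and 4.65 without spermatocyte library 4. In spermatocyte library 4, Tgif2lx1 (0 against 168 to 224 in the other spermatocyte libraries), Slxl1 (9.13 against 235 to 269), Mageb5 (0 against 78.3 to 124), Hyal5 (90.2 against 379 to 427) and Papola (754 against 1832 to 2181) were low and Aldoa (7308 against 5096 to 5404) was high. In spermatocyte library 3, Pecam1 (105 against 118 to 119), Ldha (60879 against 87104 to 92999), Ccna1 (8034 against 22254 to 25279) and the log2 ratio of Slc2a3 to Slc2a1 (8.93 against 10.74 to 10.90) were low. In spermatocyte library 1, Tdrd5 (19487 against 22392 to 22604) and Luc7l2 (8668 against 11819 to 12270) were low.

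In spermatid library 1, Spam1 (15693 against 24854 to 25818) and Pabpc1 (206763 against 326597 to 339393) were low, and Snrpb (2350 against 778 to 875) and Hnrnpl (2386 against 1226 to 1334) were high. In spermatid library 2, Pou5f1 (238 against 443 to 448), Clu (736 against 3105 to 3558) and the mean log2 level of the Sertoli list (6.43 against 7.51 to 7.64) were low, and the log2 ratio of Slc2a3 to Slc2a1 (7.27 against 5.48 to 5.75) was high.

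Spermatocyte library 4 stood apart: 541 genes with a mean log2 value above 6 were at least 2-fold below every other spermatocyte library, against 381 in library 3, 78 in library 1 and 54 in library 2, with a median departure of -1.74 in the 470 that have a GC value. Thinning spermatocyte libraries 1 and 2 to its read total, with library 3 already shallower, left 100.2% of the departure. Thinning keeps the expected normalized value of each gene, so this test could hardly change the departure and does not decide on depth. Correcting for transcript length left 101.6%, which argues against length. Library 4 lay nearer the other spermatocyte libraries than the spermatids in 92.4% of the 17910 genes called without it. That share argues against a spermatid library under a spermatocyte label. The departures of library 4 followed GC content over 13357 genes (Spearman rho 0.54, where genes are not independent). Those of library 2 ran the other way (-0.45) and those of library 3 less so (-0.16). Each departure was taken from the mean of the other spermatocyte libraries, so library 4 is part of these references. Opposite signs are thus partly forced. A GC correction left 54.9% of the departure in library 4. This lies between the bounds of under 50% and at least 80%, set before the test was run but after the departure was seen. GC bias cannot be told apart from other causes, since this share lies between both bounds. No biological explanation was tested, since the labels give no difference within the group.

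All 22 Sertoli markers and 10 of 11 Leydig markers were higher in spermatocyte libraries. A shift of all genes by a common factor is argued against by the difference of -3.35 between the median log2 fold change of the Sertoli markers and that of all tested genes, which no such factor changes. The Sertoli markers varied together over the 4 spermatocyte libraries, with a median pairwise correlation of 0.967 against a 95th percentile of 0.179 in 10000 random lists matched on mean expression, so Sertoli cell RNA in the spermatocyte fractions is a candidate explanation, with Clu, the marker with the most normalized counts, at 56079 ± 38507 normalized counts (SD, n = 4) after a sedimentation that separates cells by size. It is argued against for the bulk of the 8526 other genes called lower, whose median log2 difference between spermatocyte libraries 3 and 1 was 0.21 against 2.27 for the markers, but stays open for the 1201 of them (14.1%, against 13.6% of other tested genes) with a difference nearer to that of the markers than to 0, Slc9a2 (2.51) and Gapdh (2.13) included. The Leydig markers, with mean log2 levels of 9.69, 8.93, 9.45 and 9.66 in spermatocyte libraries 1 to 4 beside 9.53, 10.18, 11.67 and 10.53 for the Sertoli markers, did not follow them and were not tested for a source, no gene of the Sertoli list stood in another list, how many markers germ cells also express was not examined, and a difference between the cell types stays open, as untested.

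Of the spermatogonial and recombination lists, neither of which passed camera, 10 of 21 and 6 of 23 members were called higher in spermatid libraries. These 16 had a median pairwise correlation of 0.802 over the 4 spermatid libraries, just above the bound of 0.8. The 95th percentile of random lists was 0.229. The shared profile was not specific to early germ cells. The mean log2 level of the spermatogonial list fell in the order of spermatid libraries 1, 4, 3 and 2. That of the Sertoli list did so too (7.64, 7.57, 7.51 and 6.43), as did that of the X-linked genes. The Leydig, myoid and macrophage lists were also highest in library 1, with other orders below it. The test thus cannot tell RNA of early germ cells from other differences between these libraries. It leaves open whether such RNA accounts for genes such as Stra8, with 1255 ± 489 normalized counts in spermatids (SD, n = 4), and Prdm9. Rec8 and the Tex15 model, the latter 1 of the 16 genes, did not follow the spermatogonial genes. Between spermatid libraries 1 and 2 the spermatogonial genes differed by 1.10 on the log2 scale, Rec8 by -0.32 and the Tex15 model by -0.19. This does not decide on RNA of spermatogonia as the source of these 2. The difference of 1.10 may not measure such RNA, since other lists also fell from library 1 to library 2. It also rests on 2 libraries. RNA of early meiotic cells alone was not tested. A difference between the cell types stays open for these genes, as untested.

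Of 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave 17896 calls, and the highest of the others gave 0. Each other split puts both cell types in each group, so their difference adds to the spread within groups. Few calls were thus bound to follow there, and the splits do not decide whether chance gave the calls. The same held for the 9333 higher calls and the 8563 lower calls (1 of 35 each, highest other 0). For X-linked genes 1 of 35 splits gave a median as large as 2.71, and the highest other was 1.78, with the same limit. For the number of sets passing camera at the preset correlation chance is not excluded, since 8 of 35 splits gave 12 or more and the highest other gave 14. Of the other 7 splits 6 set 3 libraries of a cell type against 1, so they hold part of the difference between the cell types and say little about chance.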

How the results depend on the processing

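Equal total reads, the GC correction, genes with a GC value and leaving out spermatocyte libraries 3 and 4 together were chosen after the data were seen. No paired analysis was possible because the replicate numbers come from the order of the records. The 17896 calls ranged from 17438 to 17967 with a library left out, and edgeR called 17899 and DESeq2 17889, of which 17651 and 17628 were shared with limma in the same direction. Without spermatocyte libraries 3 and 4 there were 17823 calls, 16787 of them shared. Lower calls numbered 14333 with no filter and 5470 with the filter of 50, as more or fewer genes were tested. Genes with a GC value gave 9606 calls (6015 higher, 3591 lower), and after GC correction 10607 (4908 higher, 5699 lower), 8506 of them shared with the 17896. The share of higher calls moved from 62.6% to 46.3%, and the trend removed also carries the level of each library. With equal total reads 42.6% of calls were higher, against 52.2%.

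For camera the estimated correlation ended all 12 set calls (0 left), X-linked genes included (median 2.71, adjusted p = 0.38). The X-linked median ranged from 2.58 to 2.95 with a library left out. Pairs called ranged from 0 to 12 with a library left out, and 0 passed without spermatocyte libraries 3 and 4. With a spermatid library left out the smallest p stayed at 0.0286 but 5 pairs reached it, and with 2 spermatocyte libraries the test allows only larger p-values. Khdrbs1 stayed lower throughout, from -2.54 to -2.26 with a library left out.

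Of 228 called list members with a GC value 3 changed sign after the GC correction, Rnf17 (-0.25), Zpbp (-0.075) and Bub1 (-0.52), and of 235 called list members 0 did so with equal total reads, quantile normalization or a library left out. The other values that changed sign were not called with all libraries as deposited, and the cause was not tested. With quantile normalization they were Ldhc (-0.071), Tbpl1 (-0.033), Hspa2 (-0.094), recombination (-0.058) and cleavage factors (-0.32), and with TMM Cetn1 (4.2e-04). With equal total reads they were Ldhc (-0.36), Pabpc1 (-0.16), Hspa2 (-0.43), recombination (-0.14) and cleavage factors (-0.38). With the GC correction they were Ldhc (-0.59), Pdha1 (-0.18), Pabpc2 (-0.018), Pabpc1 (-0.43), Tbpl1 (-0.19), Hspa2 (-0.29), recombination (-0.78) and cleavage factors (-0.44), and among genes with a GC value the synaptonemal list (0.10). Without spermatocyte libraries 3 and 4 they were Ldhc (-0.16), Tbpl1 (-0.018), Hspa8 (0.012) and the ratio of Ybx2 to Ybx1 (-0.0024). With a library left out, Cetn1 ranged from -0.22 to 0.080, Hspa2 from -0.066 to 0.15, Ccna1 from -0.51 to 0.044, Ldhc from -0.071 to 0.18, Cycs from -0.78 to 0.52, Ybx2 from -0.15 to 0.13, the ratio of Papolb to Papola from -0.39 to 0.22, ribosomal proteins from -0.23 to 0.037 and the synaptonemal list from -0.32 to 0.045. Of the results for single genes, sets and pairs under the alternatives, 2244 kept their direction and side of the threshold, 76 no longer passed and 20 newly passed.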

Other observations

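Among all gene models, by normalized read counts that are not corrected for transcript length, the highest mean in spermatids was that of Akap12, a scaffold protein gene, at 452411 ± 103806 normalized counts (SD, n = 4; log2 fold change 2.38, limma adjusted p = 1.2e-06). Hk1, which encodes hexokinase, reached 226035 ± 44614 (SD, n = 4; log2 fold change 3.12, limma adjusted p = 4.7e-08). Ubb, a ubiquitin gene, had 297312 ± 37145 in spermatocytes and 324025 ± 38666 in spermatids (SD, n = 4 each; log2 fold change 0.12, limma adjusted p = 0.53). These genes were chosen after their values were seen.

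Of the 10238 tested gene models without a symbol 45.4% were called lower and 26.9% higher, against 21.1% lower and 35.6% higher of the 18497 with a symbol.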
